A study of Mus musculus with 4 samples.

How the data were processed

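Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where 3 transcription factors sit on the genome of M1, a mouse myeloid leukemia cell line grown without stimulation. Per the labels, 1 library each was made with in-house antibodies to Bach1 and Bach2 and with a commercial antibody to NF-E2 p18, another name for Mafk, and 1 further library held input DNA without antibody. Libraries were sequenced as paired ends of 51 bases, per the labels' protocols. The submitters' processing notes name CASAVA 1.8, BWA 0.7.10, MACS2 2.1.0 and the mouse build mm9, without their settings. The input library was not analysed here as a file of its own.

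The deposited data analysed here are 3 peak lists, each from 1 library. Per the file headers, each peak has a chromosome, a start, an end, a length, a summit, a pileup and a fold enrichment. The deposited pileup is a signal: the height of overlapping fragments at the summit, which was a whole number at all peaks, so the ChIP libraries had not been scaled. The deposited fold enrichment is a ratio of that pileup to the local background of the control, as the authors' peak caller gave it. It was used to describe, rank, group and test peaks within a list and to compute the background. The only test of it across lists compared the effect of Bach1 overlap between the Bach2 and Mafk lists. The peak names in the files carry a q threshold of 0.01, but the lists analysed here hold no column of p or q values. Lengths equalled end minus start plus 1 at every peak, so coordinates are counted from 1. No peak ran past the end of an mm9 chromosome, whereas 24 Bach1, 10 Bach2 and 7 Mafk peaks ran past the chromosome ends of the later build mm10, so the coordinates are given as mm9.

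The number of reads per library is unknown from these lists. The background at each summit was computed as (pileup + 1) / fold enrichment - 1, taking the pseudocount of 1 that MACS2 uses. Its lowest value recurred at 391 Bach1 peaks of 78 different pileups, 79 Bach2 peaks of 36 pileups and 481 Mafk peaks of 54 pileups (tolerance 0.001), and was 4.18, 5.61 and 5.39. At 56.1%, 67.2% and 43.9% of the peaks, the background was a whole multiple of a step of 0.689, 0.897 and 0.904 (tolerance 0.001), taken as what 1 control fragment is worth after scaling. If the 3 lists used the same control, these steps give a depth relative to the Bach1 library of 1.30 for Bach2 and 1.31 for Mafk. The lowest background divided by the shortest peak length (227, 234 and 223 bp) gave the same 1.30 and 1.31. The backgrounds of 2 lists at sites with summits within 100 bp ranked alike (Spearman rho 0.983 over 1088 Bach1 and Bach2 sites, 0.985 over 396 Bach1 and Mafk sites and 0.981 over 290 Bach2 and Mafk sites, across sites, which are not independent replicates). A Poisson p was recomputed for each peak from its pileup and this background. The ranking and threshold settings fixed before the data were examined had called for q; this p stood in for it, and its threshold was chosen after seeing the data.

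Peaks were called shared when they had at least 1 bp in common, and all peaks were merged into regions by the same rule. Shares are given with Wilson 95% intervals. Chance overlap came from 1000 random placements of the shorter list within the span of each chromosome that the 3 lists cover. Within a list, overlap with a second factor was compared between peaks with and without the remaining factor by Fisher's exact test, two-sided, and by the Mantel-Haenszel method over 3 levels of fold enrichment. Differences in median log2 fold enrichment were tested with 100000 permutations, two-sided, with Benjamini-Hochberg adjustment over 6 comparisons, and given 95% intervals from 2000 bootstrap samples of peaks. Summit distances were compared with 1000 random placements of both summits inside the overlapping peaks. Each factor had 1 library, so there is no replicate error. The p-values from random placements measure departure from that placement only. Every other p-value and interval covers the spread across peaks of these libraries only, and neighbouring peaks are not independent.

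The regions named were fixed by a rule: the 10 with peaks of all 3 factors that rank highest by Bach1 p, and the 5 that rank highest in every other class, ranked by its first named factor, leaving out the mitochondrial genome. Planned work that needs mm9 sequence or annotation was not run: distances to genes, preset gene lists and binding motifs. The gene table used here describes another build, so regions carry no gene names. Alternatives were a reciprocal overlap of 50%, summits within 100 bp, whole mm9 chromosomes for chance positions, pileup as the measure of strength, and, chosen after seeing the data, a recomputed -log10 p of at least 10, lists of equal length, peaks moved by 2 to 10 kb for chance positions, and lists without sites of high background (at least 5 times the lowest in the list, and the mitochondrial genome) or without dense groups of peaks.

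The functions were tested on simulated data. All 200 peaks planted on Bach1 summits in a simulated list of 1385 Bach2 peaks were found. In 200 simulated sets of 3873 Bach1 peaks, 98.5% of the intervals held the true odds ratio of Mafk overlap. Another 40 sets were made by shuffling the fold enrichments of the 1759 Mafk peaks, and each was tested with 500 permutations. A planted difference of 0.2 in log2 fold enrichment was called in 100%, and where none was planted a difference was called in 0%. A permutation test holds its rate of false calls on shuffled values by design. The 0% therefore checks the code only, and says nothing of neighbouring peaks that are not independent. Overlap counts were checked against bedtools 2.31.1. Computation used Python 3.11.15, scipy 1.17.1, statsmodels 0.14.6, numpy 2.4.6 and pandas 2.3.3, with chromosome lengths from GenomeInfoDb 1.38.1.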

Results

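Target regions of Bach1 and Bach2 were mapped in M1 cells, a mouse myeloid leukemia line, together with those of Mafk. Bach1 and Bach2 are related transcriptional repressors that bind DNA as heterodimers with small Maf proteins, of which Mafk is a member. Peak lists of 3 libraries, 1 per factor, were compared. The Bach1 list held 3873 peaks, the Bach2 list 1385 and the Mafk list 1759. Bach1 peaks had a median length of 349 bp (quartiles 274 to 453), a median pileup of 52 fragments (38 to 78) and a median fold enrichment over the control of 4.66 (3.44 to 6.83). Bach2 peaks had a median length of 347 bp (281 to 430), a median pileup of 66 fragments (48 to 94) and a median fold enrichment of 4.42 (3.49 to 5.90). Mafk peaks had a median length of 332 bp (266 to 395), a median pileup of 43 fragments (33 to 60) and a median fold enrichment of 4.85 (4.01 to 6.11). The strongest peaks reached a fold enrichment of 45.3 for Bach1, 24.4 for Bach2 and 17.7 for Mafk. With no second library of any factor, no difference between the lists has a replicate check.

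The first comparison asked how far the Bach1 and Bach2 peaks lie at the same sites. Most Bach2 peaks lay on a Bach1 peak: 1180 of 1385, or 85.2% (95% Wilson interval 83.2 to 87.0). In the other direction, 1172 of 3873 Bach1 peaks lay on a Bach2 peak, or 30.3% (28.8 to 31.7), and 2701 did not. Random placement of the Bach2 peaks gave a mean of 1.78 overlaps and a maximum of 7 in 1000 placements, so the observed overlap was 661 times the chance value (permutation p = 0.001, the smallest 1000 placements can give). When the Bach2 peaks were instead moved by 2 to 10 kb from their own positions, the chance mean rose to 21.9 and the ratio fell to 54.0. With each list reduced to its 1385 strongest peaks, 890 Bach2 peaks, or 64.3%, lay on a Bach1 peak. The 3 lists appear to share 1 control, so part of the overlap may come from the control, and chance positions do not account for open chromatin. Each factor also had only 1 antibody, and whether either Bach antibody also binds the other Bach factor was not tested. The overlap of peaks therefore does not by itself show that both factors bind these sites. Among the 79 Bach2 peaks scored against the genome-wide background alone, where the local control is not used, 67 overlapped Bach1, or 84.8% (75.3 to 91.1), but among the 391 such Bach1 peaks 69 overlapped Bach2, or 17.6% (14.2 to 21.7), below the 30.3% of the whole list.

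Merging all peaks gave 5410 regions. Of these, 297 held peaks of all 3 factors, 871 held Bach1 and Bach2, 121 held Bach1 and Mafk, and 2 held Bach2 and Mafk without Bach1. With a reciprocal overlap of 50% required, 177 sites held all 3 factors, and with summits within 100 bp 284 did. Single factors held 2580 regions for Bach1, 203 for Bach2 and 1336 for Mafk.

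**Figure D1:**
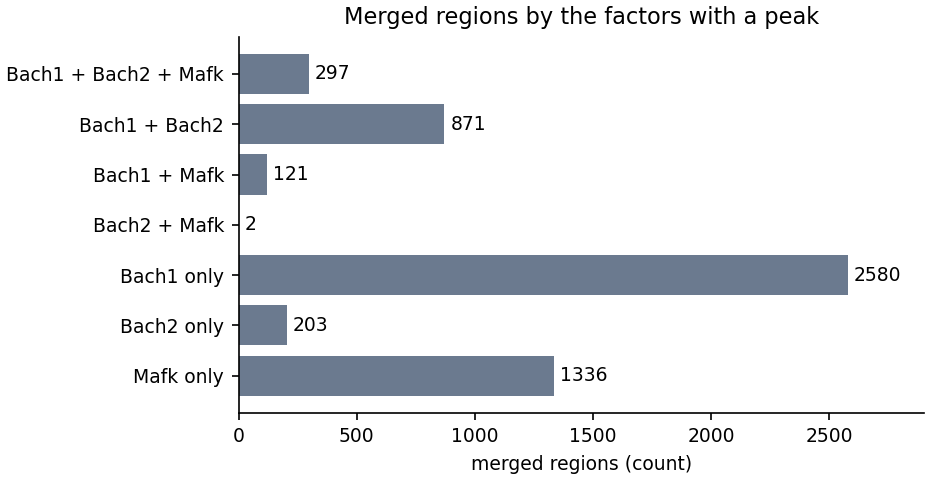
Number of merged regions (x axis, count) for each of the 7 combinations of factors with a peak (y axis); each bar is 1 class of the 5410 regions. Few regions held a Bach2 peak without a Bach1 peak (203 alone and 2 with Mafk), whereas 2580 regions held Bach1 peaks alone and 1336 held Mafk peaks alone. The 297 regions with all 3 factors became 177 sites with a reciprocal overlap of 50% and 284 with summits within 100 bp.

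Mafk peaks were compared with those of both Bach factors because Mafk is their dimer partner. Of 1759 Mafk peaks, 421 lay on a Bach1 peak, or 23.9% (22.0 to 26.0), and 302 on a Bach2 peak, or 17.2% (15.5 to 19.0). Of the Bach1 peaks, 418 lay on a Mafk peak, or 10.8% (9.85 to 11.8), and of the Bach2 peaks 300 did, or 21.7% (19.6 to 23.9). The remaining 1336 Mafk peaks, 76.0% (73.9 to 77.9), lay on no called peak of either Bach factor, which does not show that these factors were absent there. The Mafk shares moved with the control background: among the 481 Mafk peaks at the lowest background, 7.90% (5.81 to 10.7) lay on a Bach1 peak and 4.57% (3.04 to 6.83) on a Bach2 peak, and among the 55 at 5 times the lowest or more, 72.7% and 60.0% did. At the lowest background 43 of 391 Bach1 peaks, or 11.0% (8.27 to 14.5), and 25 of 79 Bach2 peaks, or 31.6% (22.4 to 42.5), lay on a Mafk peak. The overlap was 136 times the chance value for Bach1 and Mafk (mean 3.10 by chance) and 372 times for Bach2 and Mafk (mean 0.807 by chance), each with a permutation p of 0.001, the smallest 1000 placements can give. With peaks moved by 2 to 10 kb these ratios were 72.1 and 114. Chromosome Y held only 1 Bach1 and 1 Mafk peak, so the span for placement there was set by these peaks themselves. This can force an overlap and lower the ratio of Bach1 and Mafk. Over whole mm9 chromosomes their chance mean was 2.01 and the ratio 209.

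Bach1 peaks with Bach2 overlapped Mafk more often than Bach1 peaks without Bach2. Among Bach1 peaks, 297 of 1172 with Bach2 overlapped Mafk, or 25.3% (22.9 to 27.9), against 121 of 2701 without Bach2, or 4.48% (3.76 to 5.33). The odds ratio was 7.24 (5.78 to 9.06; Fisher's exact test across peaks, two-sided, p = 7.9e-75). Within 3 levels of Bach1 fold enrichment, the pooled odds ratio was 4.24 (3.30 to 5.44; Mantel-Haenszel test across peaks, n = 3873, p = 1.6e-32). Among Bach2 peaks, 298 of 1180 with Bach1 overlapped Mafk, or 25.3% (22.9 to 27.8), against 2 of 205 without Bach1, or 0.976% (0.268 to 3.49). This odds ratio was 34.3 (8.47 to 139; Fisher's exact test across peaks, two-sided, p = 7.2e-21), and 22.4 (5.67 to 88.8) within 3 levels of Bach2 fold enrichment. Of the 302 Mafk peaks with Bach2, 300 also lay on a Bach1 peak.

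Within the Bach1 list, shared sites were the stronger ones. Bach1 peaks with Bach2 had a median fold enrichment of 7.37 (n = 1172 peaks) against 4.09 without (n = 2701), a difference of 0.85 in log2 (95% interval 0.78 to 0.92). Those with Mafk had 9.07 against 4.49, a difference of 1.01 (0.92 to 1.19), which was 0.64 (0.54 to 0.85; 7.14 against 4.58) with a reciprocal overlap of 50%. The 297 Bach1 peaks with both Bach2 and Mafk had a median of 12.2 (quartiles 7.72 to 17.4), and the 2580 with neither had 4.05 (3.17 to 5.34). With the list divided into 5 groups by fold enrichment, from the weakest to the strongest group of Bach1 peaks, the share on a Bach2 peak went from 7.35% (5.72 to 9.41) to 72.5% (69.3 to 75.5), and that on a Mafk peak from 2.06% (1.27 to 3.33) to 32.3% (29.1 to 35.6). Bach2 peaks with Bach1 had a median fold enrichment of 4.69 against 3.53 without, a difference of 0.41 (0.32 to 0.48), and Bach2 peaks with Mafk 5.52 against 4.22, a difference of 0.39 (0.30 to 0.50). In the strongest of 5 such groups of Bach2 peaks, 272 of 277 lay on a Bach1 peak, or 98.2% (95.8 to 99.2), and in the weakest 193 of 277, or 69.7% (64.0 to 74.8).

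Mafk peaks went the other way in fold enrichment. Those with Bach1 had a median of 4.39 against 5.01 without, a difference of -0.19 in log2 (-0.26 to -0.14), and those with Bach2 had 4.24 against 5.01, a difference of -0.24 (-0.32 to -0.16). In pileup the direction turned: Mafk peaks with Bach1 had a median of 57 fragments and those without had 40, and the control background was 2.18 times the lowest in the list at the former and 1.17 times at the latter. All 6 of these differences in fold enrichment had an adjusted permutation p of 1e-05, the smallest 100000 permutations can give.

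**Figure D2:**
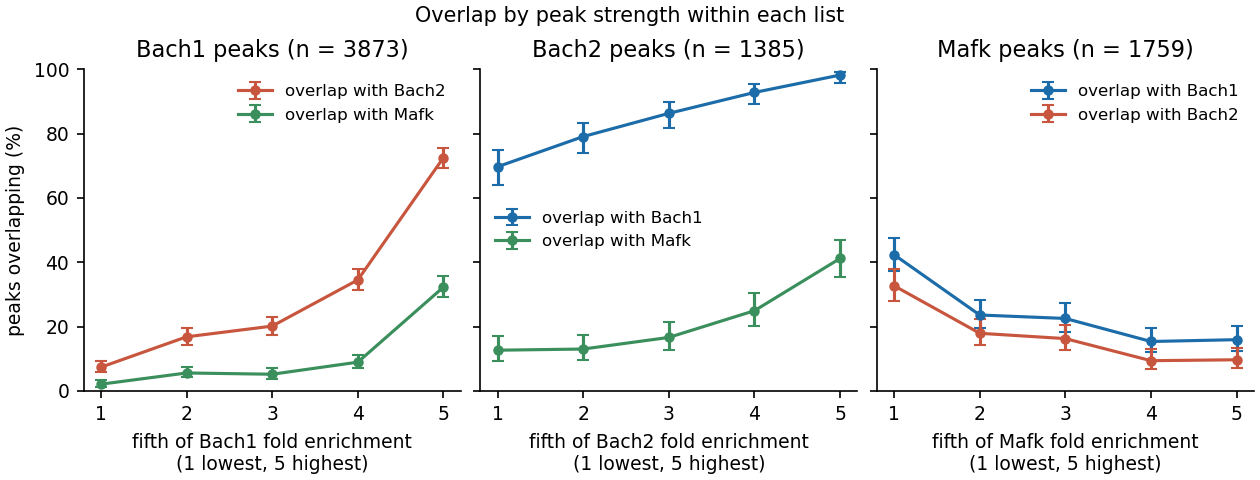
Share of peaks that overlap another factor (y axis, %) by group of fold enrichment within the list (x axis, 1 lowest to 5 highest), in 1 panel per list; points are shares of the peaks in that group and bars are Wilson 95% intervals. The share rises with strength in the Bach1 list (to 72.5% for Bach2) and the Bach2 list (to 98.2% for Bach1), and falls in the Mafk list from 42.3% to 15.9% for Bach1; shares by pileup were not computed, and the median pileup was higher in Mafk peaks with Bach1 (57) than without (40).

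At shared sites the summits lay close together. The median distance between the nearest summits was 22 bp for Bach1 and Bach2 (quartiles 10 to 43, 1172 peaks), 19 bp for Bach1 and Mafk (7 to 38, 418 peaks) and 19 bp for Bach2 and Mafk (9 to 37, 300 peaks). Summits lay within 50 bp at 79.8% (77.4 to 82.0), 85.6% (82.0 to 88.7) and 83.0% (78.3 to 86.8) of these peaks. Summits placed at random inside the same peaks gave median distances of 130, 131 and 110 bp on average (permutation p = 0.001 for each pair, the smallest 1000 placements can give). These placements were even over the peak length, whereas a true summit stands where the pileup is highest. Peaks that merely overlap could also give shorter distances, so the p-value excludes even placement only.

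**Figure D3:**
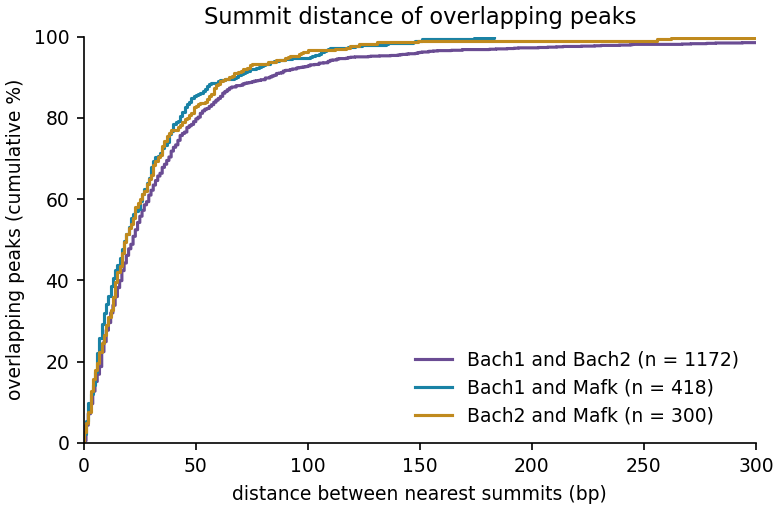
Cumulative share of overlapping peaks (y axis, %) by distance between the nearest summits of 2 factors (x axis, bp, shown to 300), 1 line per pair. All 3 lines rise steeply, with medians of 22, 19 and 19 bp.

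Of the regions with all 3 factors, the highest ranking was on chromosome 8 at 77612939 to 77614159 (mm9), with a fold enrichment of 33.0 for Bach1, 11.4 for Bach2 and 7.70 for Mafk and summits at 77613621, 77613613 and 77613622. A second region of the 10 highest ranking lay nearby, at 77605569 to 77608487, with 23.1, 12.4 and 6.87. A Bach1 peak at 77617280 to 77617749 (8.22) with a Bach2 peak inside it (3.27) followed, without a Mafk peak; this site was chosen after its values were seen. On chromosome 19, the region at 10052713 to 10053459 had a fold enrichment of 32.0 for Bach1, 20.1 for Bach2 and 5.78 for Mafk, and that at 59052868 to 59053937 had 35.7, 10.1 and 6.67. On chromosome 7, the region at 111009212 to 111010083 had 43.0, 19.9 and 7.67, and that at 28167760 to 28168745 had the highest Bach1 value of any peak, 45.3, with 9.14 for Bach2 and 6.35 for Mafk. The others were on chromosome 15 at 97616603 to 97617843 (27.7 for Bach1), chromosome 3 at 146317596 to 146318583 (38.2), and chromosome 5 at 144175260 to 144176402 (22.6) and 124501789 to 124502735 (22.8).

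**Figure D4:**
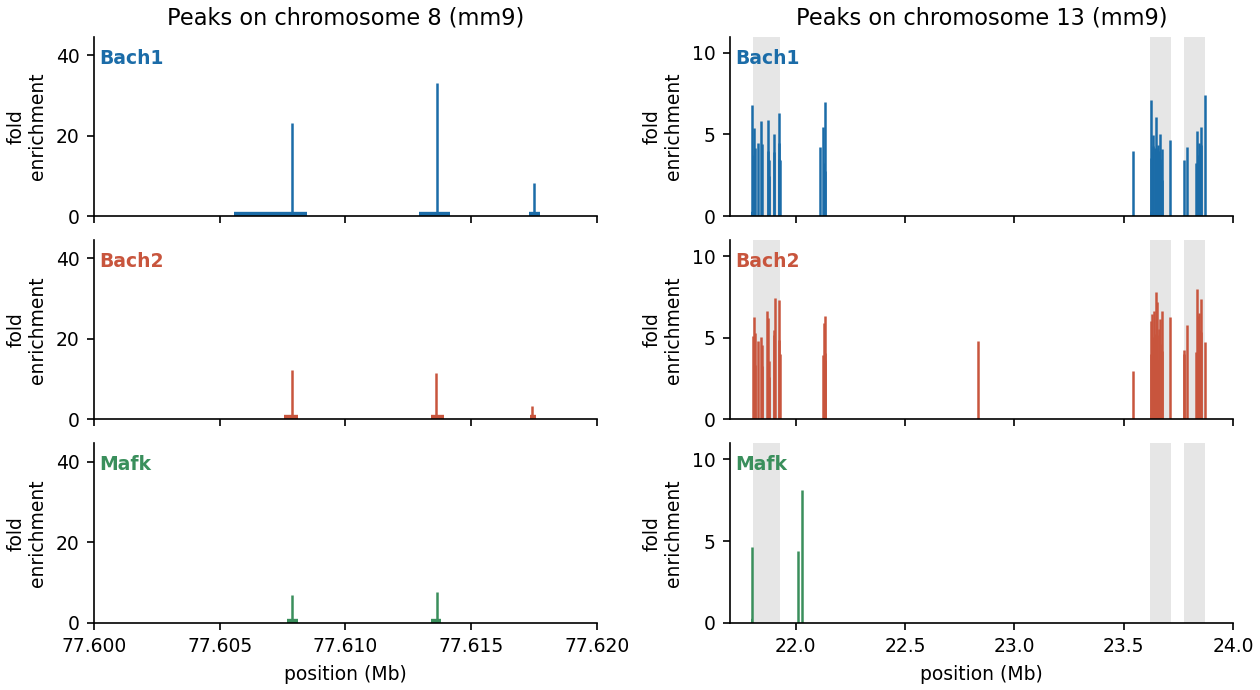
Peaks of the 3 factors (rows) on chromosome 8 around 77.6 Mb (left) and chromosome 13 from 21.7 to 24.0 Mb (right), in mm9; x axis, position in Mb; y axis, fold enrichment; thin lines stand at summits and thick bars span the peaks. On chromosome 8 the pair of strongest sites holds all 3 factors; on chromosome 13 the grey spans are the 3 dense groups of Bach2 peaks, in which Bach1 also has peaks and Mafk has none, the nearest Mafk peak lying left of the first span.

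Regions held by Bach1 and Bach2 without Mafk included chromosome 14 at 67807376 to 67807965, with a fold enrichment of 21.0 for Bach1 and 8.09 for Bach2, and chromosome 13 at 36294741 to 36295409, with 26.2 and 14.1. The others of the 5 were on chromosome 5 at 116102985 to 116103521 (16.1 for Bach1) and 149765734 to 149766517 (12.8), and on chromosome 10 at 18814162 to 18814690 (13.7). The 5 highest-ranking regions of Bach1 and Mafk without Bach2 had a Bach1 fold enrichment between 8.01 and 12.5, led by chromosome 9 at 31994114 to 31994681 (9.92 for Bach1 and 5.17 for Mafk). The regions of Bach2 and Mafk without Bach1 were on chromosome 10 at 103679327 to 103679578 (5.17 for Bach2 and 5.84 for Mafk) and chromosome 1 at 168451231 to 168451561 (5.18 and 3.88).

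Strong peaks of 1 factor alone were found for each. The highest-ranking for Bach1 were on chromosome 4 at 136604378 to 136604877 (fold enrichment 14.7), chromosome 9 at 123275841 to 123276349 (14.6), chromosome 3 at 97461970 to 97462568 (14.1), chromosome 16 at 18248333 to 18249189 (12.0) and chromosome 11 at 101303356 to 101303996 (7.52, where the control background was 10.4 times the lowest). The highest-ranking for Mafk were on chromosome 16 at 22714179 to 22714896 (17.7, the highest Mafk value of any peak) and 36516252 to 36517160 (15.4), chromosome 15 at 80328192 to 80328678 (12.2), chromosome 3 at 130071073 to 130071741 (13.7) and chromosome 6 at 5379765 to 5380413 (17.6). Those for Bach2 reached 10.6, on chromosome 17 at 68454746 to 68455146 and chromosome 4 at 138058716 to 138059338, and included chromosome 4 at 133400165 to 133400552 (6.09), chromosome 11 at 54987153 to 54987562 (9.83) and chromosome 7 at 87975393 to 87975768 (5.08). A peak missing from a list was below that list's threshold and is not shown to be unbound.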

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

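The test of the difference between lists was chosen after the result was seen. In fold enrichment, the effect of Bach1 overlap differed between the Bach2 and Mafk lists. Bach2 peaks on a Bach1 peak had a mean log2 fold enrichment 0.42 above that of the other Bach2 peaks, while Mafk peaks on a Bach1 peak differed from the other Mafk peaks by -0.22. The difference between these effects was 0.64 (interaction term, 10000 permutations of residuals, p = 0.0001, the smallest they can give), and it was tested in fold enrichment alone. That test took the peaks of both lists as independent, although 300 Bach2 peaks lay on a Mafk peak. The opposite directions were not seen with other measures: the difference in medians was 0.43 in log2 pileup for Bach2 peaks (95% interval 0.31 to 0.57) and 0.51 for Mafk peaks (0.42 to 0.58), and in log2 of the recomputed -log10 p it was 0.78 and 0.22. Explanations were tested on the medians of the Mafk list, where the difference was -0.19. Within quartiles of the control background the mean difference was -0.0105 (95% interval -0.074 to 0.064). A higher control background at the shared sites, 2.18 against 1.17 times the lowest, may therefore account for the lower fold enrichment there. However, this background is the denominator of fold enrichment and was computed from it and the pileup. A higher pileup with a lower fold enrichment gives a higher background by arithmetic, so the test is not independent evidence of a cause. Sites of very high background were not the whole cause: without peaks at 5 times the lowest background or more, the difference was still -0.15 (-0.20 to -0.09). Why the control is higher at shared sites stays open, as does any difference in how Mafk binds with and without a Bach partner, which was not tested.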

How the results depend on the processing

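The tests with the recomputed p, with lists of equal length, with peaks moved by 2 to 10 kb and without sites of high background or dense groups of peaks were chosen after seeing the data. Of 67 alternative values, 63 kept their direction and their side of the threshold or stayed within 1.5 times the main count. With lists of equal length, 279 Mafk peaks overlapped Bach1 instead of 421, which follows from the smaller lists. With a reciprocal overlap of 50%, the sites with all 3 factors fell from 297 to 177, whereas with summits within 100 bp 284 were left. Where all 3 factors overlapped, the median length was 557 bp for Bach1 peaks and 305.5 bp for Mafk peaks. The reciprocal rule left 295 of the 421 Mafk peaks on Bach1, and 280 of the 300 Bach2 peaks on Mafk. Peaks of unlike length can fail such a rule, but the cause was not tested. The lower strength of Mafk peaks on Bach1 reversed with pileup as the measure (0.51 in log2) and with the recomputed -log10 p (0.22 in log2). The ratio to chance kept its direction but not its size: for Bach1 and Bach2 it ranged from 54.0 with peaks moved by 2 to 10 kb to 2578 with summits within 100 bp, for Bach1 and Mafk from 72.1 to 243 and for Bach2 and Mafk from 114 to 1368 under the same settings. The 243 for Bach1 and Mafk used the placement spans of the main setting, which can force an overlap on chromosome Y. The odds ratio of Mafk at Bach1 sites with Bach2 ranged from 4.24 to 8.43, the lowest when stratified by strength. The planned threshold on q, chance positions matched on distance to genes, gene lists and motifs were not run, for want of q values and of mm9 annotation in the sources used here. No paired analysis was possible because each factor has 1 library, and for the same reason no replicate could be left out. Depth limits the lists: a site near the threshold in 1 library can be missed in another.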

Other observations

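The tests in this part were chosen after the patterns were seen. Bach2 peaks were crowded on chromosome 13. Of the chains of peaks spaced by at most 50 kb, 3 held 10 or more Bach2 peaks, all on this chromosome in mm9: 21807266 to 21927105 (18 peaks), 23622831 to 23714437 (17 peaks) and 23775162 to 23870655 (12 peaks). Of these 47 Bach2 peaks, 46 lay on a Bach1 peak and 0 on a Mafk peak. This depends on where the spans end: the chain of Bach1 peaks at the first of them starts earlier, at 21798604 to 21927160, and 1 of its 17 Bach1 peaks lay on a Mafk peak. The Bach2 peaks were long, with a median of 941 bp against 342 bp for other Bach2 peaks, and 35 of them reached 800 bp, against 25 of all others. Their median fold enrichment was 5.24 against 4.41. For the 43 Bach1 peaks in these spans it was lower than for other Bach1 peaks, 4.21 against 4.67. The Bach1 and Bach2 summits there were also farther apart, with a median of 164 bp over 43 Bach1 peaks against 21 bp elsewhere.

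The control argues only against a large gain of copies or a very high control background as the cause of these groups. The median background of their Bach2 peaks was 1.22 times that of the others (95% interval 1.14 to 1.33). This was under the value of 2 below which it was taken as too small. The background was still raised, with medians of 3.04 to 3.18 times the lowest in the 3 groups and 2.56 times in the whole Bach2 list. Input DNA cannot show background that arises only with an antibody. For the Bach1 peaks in these spans the median background was 1.33 times that of other Bach1 peaks. Whether Mafk is missing because the sites are weak may depend on the yardstick. From Bach1 peaks of like fold enrichment elsewhere, 2.63 of the 43 Bach1 peaks would overlap Mafk, and 0 did within the spans of the Bach2 peaks (exact Poisson binomial lower tail p = 0.065). From Bach2 peaks of like fold enrichment, 10.99 of 47 would, and 0 did (exact Poisson binomial lower tail p = 2.7e-06), although neighbouring peaks in 3 groups are not independent. A different mode of binding over these spans stays an untested hypothesis. The Bach1 and Bach2 libraries were made with in-house antibodies and the Mafk library with a commercial one. Antibody and factor therefore cannot be told apart at these spans.

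The Bach1 list was 2.80 times as long as the Bach2 list. Greater depth is an unlikely reason, since the Bach1 library had 0.768 times the depth of the Bach2 library by the scaling of their control, if they share it. Without sites at 5 times the lowest background or more, 3465 Bach1 and 1289 Bach2 peaks were left, still a ratio of 2.69. Antibody and factor cannot be told apart, because each factor has 1 library made with 1 antibody.

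Peaks were sparse on the X chromosome: 70 for Bach1, 14 for Bach2 and 16 for Mafk. Per Mb of mm9 sequence this was 0.273 times the autosomal density for Bach1 (95% exact binomial interval 0.213 to 0.346), 0.151 for Bach2 (0.083 to 0.255) and 0.136 for Mafk (0.078 to 0.222). The sparsest autosomes had 0.935 Bach1 peaks per Mb (chromosome 14), 0.305 Bach2 peaks and 0.445 Mafk peaks (chromosome 12), against 0.420, 0.084 and 0.096 on X. The number of X copies in these cells and how well reads map to X were not examined. Fewer peaks called on X therefore do not show that the factors avoid it.

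Bach peaks lay near one another more often than Mafk peaks did: 16.1% of Bach1 peaks (95% interval 15.0 to 17.3) and 13.3% of Bach2 peaks (11.6 to 15.2) had another peak of their list within 10 kb, against 3.81% of Mafk peaks (3.01 to 4.81), where random positions gave 3.30%, 1.21% and 1.52%. Without the dense groups of Bach2 peaks on chromosome 13 and sites of high background the shares were 13.6%, 9.74% and 3.81%. A chain of 10 Bach1 peaks on chromosome 19, at 5791954 to 5850545, was not among the groups removed. Among the sites of high background, 35 Bach1 peaks lay on chromosome 9 between 3000115 and 3038220, with a median fold enrichment of 1.52 and a background 57.2 times the lowest, and 0 of them overlapped Bach2 or Mafk.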
